A study of Homo sapiens with 12 samples.

How the data were processed

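Small RNA libraries of 12 human samples were analysed, comprising sorted alpha cells and sorted beta cells (1 library each), whole islets at 1, 5.56 and 16.7 mM glucose (1 library each), and whole islets of 3 control and 4 T2D donors (1 library each). Per the labels' protocols, small RNA was isolated with the mirVana kit, inserts of 22 to 30 nt were selected on a gel, and adapters were to be trimmed before alignment. The sorted cells and the glucose series were prepared with the TruSeq small RNA kit and the donor islets with the older v1 kit, per the labels, so values were compared only within each experiment, except the summed levels of 4 miRNA families encoded by several genes. The aligner, the counting tool, the miRNA annotation and the genome build of the alignment were not given in the sources used here. In the donor table the columns could be mapped to the control and T2D groups but not to single donors, and libraries are named as the table numbers them.

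Expression was deposited as reads-per-million values (RPM) for all 12 libraries, per the file headers. In the donor and sorted-cell tables no value was 0 and the smallest value of each column recurred, so that miRNAs without reads stood at about 1 read. The glucose table held zeros. The log2 values of the deposited donor table were, per the file headers, group means of quantile-normalized values with their difference and mean, computed by the authors, beside a false discovery rate in percent whose test was not given in the sources used here. The deposited sorted-cell table also held the authors' ratio of alpha over beta cells from quantile-normalized values. The authors' log2, false discovery rate and ratio values served only for comparison, and 14 quantile-normalized columns were not used.

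Depth was estimated from the RPM value of 1 read in each library. Low values that were whole multiples of 1 read, within 0.1 read and up to 20 reads, made up 86.9% to 94% of low values in the donor table, 95.2% in the beta cell library and 100% in the glucose libraries. In the alpha cell library, where 1 read was close to the rounding of the values, this share was not taken. Instead 88.3% of 522 low values equalled a rounded whole multiple, where 43.2% of all values of 2 decimals do, and the depth had been fitted to values of this kind. Because the values were RPM and not counts, the donor comparison used the alternative set for normalized values before the data were examined, which was limma in place of a count test. miRNAs with at least 5 RPM in at least 3 libraries were kept, RPM values were scaled by TMM factors (edgeR 4.0.16, calcNormFactors), and log2(scaled RPM + 1) was fitted with limma 3.58.1 (group only, eBayes with trend and robust, two-sided) in R 4.3.3. Benjamini-Hochberg adjustment covered all miRNAs tested, with a threshold of 0.05. Means and SDs are of scaled RPM, and log2 fold changes are T2D minus control.

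Before the data were examined 20 lists were fixed. They held the 14q32 DLK1-MEG3 miRNAs, islet-enriched miRNAs, the miR-183 cluster, the miR-200 family, markers of acinar, red blood, white blood, mesenchymal and endothelial cells and of muscle and liver, the C19MC cluster, miRNAs of other imprinted loci, miR-17-92 with its paralogs, the let-7/98, miR-29, miR-30 and miR-34 families, inflammation-associated miRNAs, the activity- and cAMP-responsive miR-132 and miR-212, and the X-linked miR-506 cluster. Lists with at least 3 tested members were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry. Members were also counted as adjusted over the list alone. The share of reads from each list was compared by an exact permutation test over the 35 splits of the 7 libraries, adjusted over the lists.

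The sorted cells and the glucose levels had 1 library per condition, and no test between conditions was made. Ratios of RPM were taken for miRNAs with a mean of at least 50 RPM, with the exact (Clopper-Pearson) 95% interval of the split of the reads. miRNAs at least 2-fold apart were counted, and the median log2 ratio of each list with at least 3 members was placed among 10000 random lists of the same size matched over 10 level bins. These steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Positions were taken by gene symbol from GENCODE release 29 (GRCh38).

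miRNAs were named by a rule set before the data were examined. In the donor comparison it took the 10 largest changes each way past the threshold, or the 5 smallest p if fewer than 5 passed, and up to 15 members of the 14q32 list past it. In the other experiments it took the 10 largest ratios each way. In each experiment it added the 5 most abundant miRNAs, the 2 to 4 most abundant members of each list described, and miR-375, miR-7, miR-184, miR-376a, miR-432, miR-127, miR-136, miR-495, miR-411, miR-379, miR-132, miR-212, miR-216a, miR-217 and miR-451.

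The steps were tested on simulated data. With 4 and 3 simulated libraries and a spread of 0.91 on the log2 scale, the donor comparison recovered 7% of changes of 1 on the log2 scale, 39.4% of changes of 2 and 85% of changes of 3, with 3.6% false calls. In each run 200 miRNAs were changed, with 400.6 tested on average. Recovery after adjustment is lower where fewer miRNAs change, so these shares may be too high for the donor data. In 50 simulated runs a list without change was called in 6% and a halved list in 100%. Of 40 random lists without a shift, 7.5% fell outside the middle 95% of percentiles, and 97.5% lay above it with a shift of 1. The intervals held the true ratio in 95% to 96.8% of draws.

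Alternatives set before the data were examined were other scalings (RLE, library totals alone, totals without the most abundant miRNA, and TMM for the single libraries), no filter or a filter of 10 RPM, limma-voom with sample weights on estimated reads, a threshold of 0.1, minimum means of 10 and 200 RPM, and leaving out each donor library. Chosen after the data were seen were pseudocounts of 0.5 and 5, a common floor at the value of 1 read in the shallowest library, quantile normalization, and summing entries that differ only in the gene copy. These share 1 mature sequence in 1 arm, taken as the arm most abundant in the sorted cells.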

Results

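MicroRNAs (miRNAs), short RNAs that repress messenger RNAs, were measured by small RNA sequencing in 12 libraries of human pancreatic islets and islet cells. Islets are the clusters of endocrine cells in the pancreas, in which beta cells secrete insulin and alpha cells secrete glucagon. In the first experiment 1 library was made from sorted alpha cells and 1 from sorted beta cells. In the second, islets from 3 donors were kept at 5.56 mM glucose for 6 hours, divided, and cultured for 16 hours at 1, 5.56 or 16.7 mM glucose, with 1 library per level. In the last, whole islets of 3 control donors and 4 donors with suspected or established type 2 diabetes (T2D) gave 1 library each. The series title names the imprinted DLK1-MEG3 locus on chromosome 14q32, whose miRNAs were therefore the first list examined in each experiment, and a list taken from the title of the study of these samples is not independent evidence.

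The depth implied by the values, in million-read units (M), was 43.76 for the alpha cell library, 16.19 for the beta cell library, and 5.94, 6.62 and 13.76 for 1, 5.56 and 16.7 mM glucose. It was 2.45 to 5 M in the 4 T2D libraries and 0.7 to 1.31 M in the 3 control libraries, so that every control library was shallower than every T2D library. In reads-per-million (RPM) units, 1 read was worth 0.2001 to 0.409 RPM in the T2D libraries and 0.764 to 1.4201 RPM in the controls. The 5 most abundant miRNAs took 63.0% to 79.0% of the reads in the 7 donor libraries, 64.6% in alpha cells, 56.3% in beta cells and 48.3% to 54.5% in the glucose libraries. The alpha cell depth is the least certain, since 1 read there was worth 0.0228 RPM in values given to 0.01. Counting intervals are given at 95%, rest on these depths and cover counting error only, since amplified reads are not independent molecules.

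The comparison of beta and alpha cells asked which miRNAs separate the main endocrine cell types of the islet. miRNAs of the 14q32 locus stood far higher in the beta cell library. All 30 of the 14q32 miRNAs with a mean of at least 50 RPM were higher there, 28 of them by at least 2-fold, and their median was 7.12-fold higher (median log2 ratio 2.83). The locus supplied 10.8% of the reads in beta cells (10.8% to 10.8%, Clopper-Pearson interval) and 0.778% in alpha cells (0.775% to 0.780%). The cluster of miR-183, miR-96 and miR-182 (the miR-183 cluster), expressed in sensory and neuroendocrine cells, was also higher in beta cells, whereas miR-192-5p, miR-181a-1-5p and miR-708-5p were higher in alpha cells.

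Among the 211 miRNAs with a mean of at least 50 RPM, which held 99.6% of the reads, 72 were at least 2-fold higher in the beta cell library and 40 at least 2-fold lower. The counting interval excluded 1 for each of them, which the 2-fold bound and the depth fix in advance. Of the 72, 28 belonged to the 14q32 list, and of the 40, 0 did. The ratio was highest for miR-136-5p, with 736 RPM in beta cells and 17.9 RPM in alpha cells, a 41.0-fold difference (38.2 to 44.1). It was followed by miR-183-5p (31.3-fold), miR-96-5p (26.6-fold), miR-323a-3p (23.4-fold), miR-411-5p (22.2-fold), miR-431-3p (22.2-fold), miR-127-3p (21.5-fold), miR-493-5p (20.7-fold), miR-379-5p (19.3-fold) and miR-127-5p (18.7-fold). The most abundant of these was miR-127-3p, at 87461 RPM in beta cells and 4075 RPM in alpha cells. miR-432-5p reached 1195 RPM against 112 RPM. miR-376a-1-3p (84.9 against 8.47 RPM) and the entry miR-495 (30.2 against 6.76 RPM) lay below the minimum mean and were not counted.

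In the other direction, miR-708-5p was 16.3-fold higher in alpha cells (14.01 to 19.1), at 172 against 10.6 RPM. miR-362-5p was 12.9-fold higher, miR-181a-1-5p 12.6-fold, miR-500a-3p 10.9-fold, miR-153-2 8.53-fold, miR-194-2-5p 7.84-fold, miR-192-5p 7.20-fold, miR-181b-2-5p 5.60-fold, miR-222-3p 5.14-fold and miR-1224-5p 4.96-fold. Some of these are single entries of miRNAs that several genes encode with 1 mature sequence. Summed over the genes, a step chosen after the values were seen, the ratio was 7.33-fold for miR-181a-5p and only 1.78-fold for miR-153, whose other entry, miR-153-1, went the opposite way (320.37 RPM in alpha and 750.9 RPM in beta cells). With all such entries summed, 67 miRNAs were at least 2-fold higher in beta cells and 38 at least 2-fold lower. miR-192-5p had the highest level among them, with 88589 RPM in alpha cells and 12298 RPM in beta cells. miR-375, an islet miRNA that restrains insulin secretion, was the most abundant miRNA in both libraries, at 438333 RPM in alpha cells and 338582 RPM in beta cells (log2 ratio −0.37). let-7a-5p stood at 42180.1 and 63789.6 RPM and miR-7-2-5p, another islet miRNA, at 40879 and 37208 RPM, in alpha and beta cells respectively. miR-184 stood at 1362 RPM in alpha cells and 1604 RPM in beta cells, a log2 ratio of 0.24 that turned to −0.13 with trimmed-mean scaling (TMM).

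By list, the 3 arms of the miR-183 cluster over the minimum had a median log2 ratio of 4.73, at percentile 99.71 of 10000 random lists matched for size and level. miR-182-5p of this cluster was 10.9-fold higher in beta cells. The 14q32 median lay at percentile 100, where 95% of the random lists fell between −0.04 and 1.24. The random lists treat miRNAs as independent, which arms of 1 hairpin and neighbours in 1 cluster may not be. Percentiles of such lists, here and in the glucose series, can thus be too extreme. The 5 members of the miR-29 family had a median of 2.02 (percentile 98), of which miR-29c-3p was the most abundant at 2778 against 683 RPM and miR-29b-1-3p had the highest ratio (13.3-fold, and 7.26-fold summed with miR-29b-2-3p, of the same sequence). With such entries summed the median was 1.416 over 4 members. Some miRNAs from the marker lists of other pancreatic and blood cells also had reads. These alone do not show such cells in the sorts, since other members of the acinar and red blood cell lists were low. miR-148a-3p, abundant in acinar cells of the exocrine pancreas, stood at 24326 RPM in beta cells and 3227 RPM in alpha cells, miR-217 at 91.4 and 41.2 RPM, and the red blood cell marker miR-486-5p at 8239 and 1673 RPM, while miR-451a was at 0.37 and 0.25 RPM. The white blood cell marker miR-342-3p was at 901 and 922 RPM, the mesenchymal marker miR-143-3p at 361 and 253 RPM, and the endothelial miRNA list, miR-126, had 1 arm over the minimum with a log2 ratio of 0.31.

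The remaining lists gave smaller medians. These were 0.80 for the islet-enriched list (13 members, percentile 83.86), −0.10 for the epithelial miR-200 family (8, percentile 28.24), −0.43 for miR-17-92 and its paralogs (10, percentile 10) and 0.16 for let-7/98 (11, percentile 50.26). They were 0.09 for the miR-30 family (8, percentile 23.67), −0.19 for the inflammation-associated list (4, percentile 16.48) and 0.46 for the activity- and cAMP-responsive miR-132 and miR-212 (4, percentile 43.16). With the entries of 1 mature sequence summed, the median went to 0.24 for the islet-enriched list, −0.64 for miR-17-92 and −0.22 for miR-30, the last turning direction. Both members of the list of other imprinted loci, miR-335-3p and miR-335-5p, were higher in beta cells (log2 ratio 0.25 and 1.08), and so was miR-34a-5p (1.48). No member of the muscle and liver, chromosome 19 (C19MC) or X-linked miR-506 lists reached the minimum. With 1 library per cell type the spread between sorts was not measured. TMM moved the median of all miRNAs from 0.32 to −0.05 and the 14q32 median from 2.83 to 2.46.

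The annotation (GENCODE release 29, GRCh38) places the 52 hairpin genes found for the list on the plus strand of chromosome 14 between 100852390 and 101066801, on the distal side of the non-coding gene MEG3 (100779410 to 100861031), with the first hairpin, MIR770, inside MEG3. The paternally expressed protein-coding gene DLK1 lies at 100725705 to 100738224. MIR127 (100882979 to 100883075) and MIR136 (100884702 to 100884783) lie antisense to RTL1 (100879753 to 100903722, minus strand). MIR495 (101033755 to 101033836) lies within the span of the non-coding gene MEG8 (100894770 to 101038859), and MIR539 (101047321 to 101047398) lies between MEG8 and MEG9 (101064151 to 101072937). Outside the locus, MIR375 lies on chromosome 2 at 219001645 to 219001708, MIR30A on chromosome 6 at 71403551 to 71403621, MIR7-3 on chromosome 19 at 4770670 to 4770779 and MIR183 on chromosome 7 at 129774905 to 129775014.

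**Figure D1:**
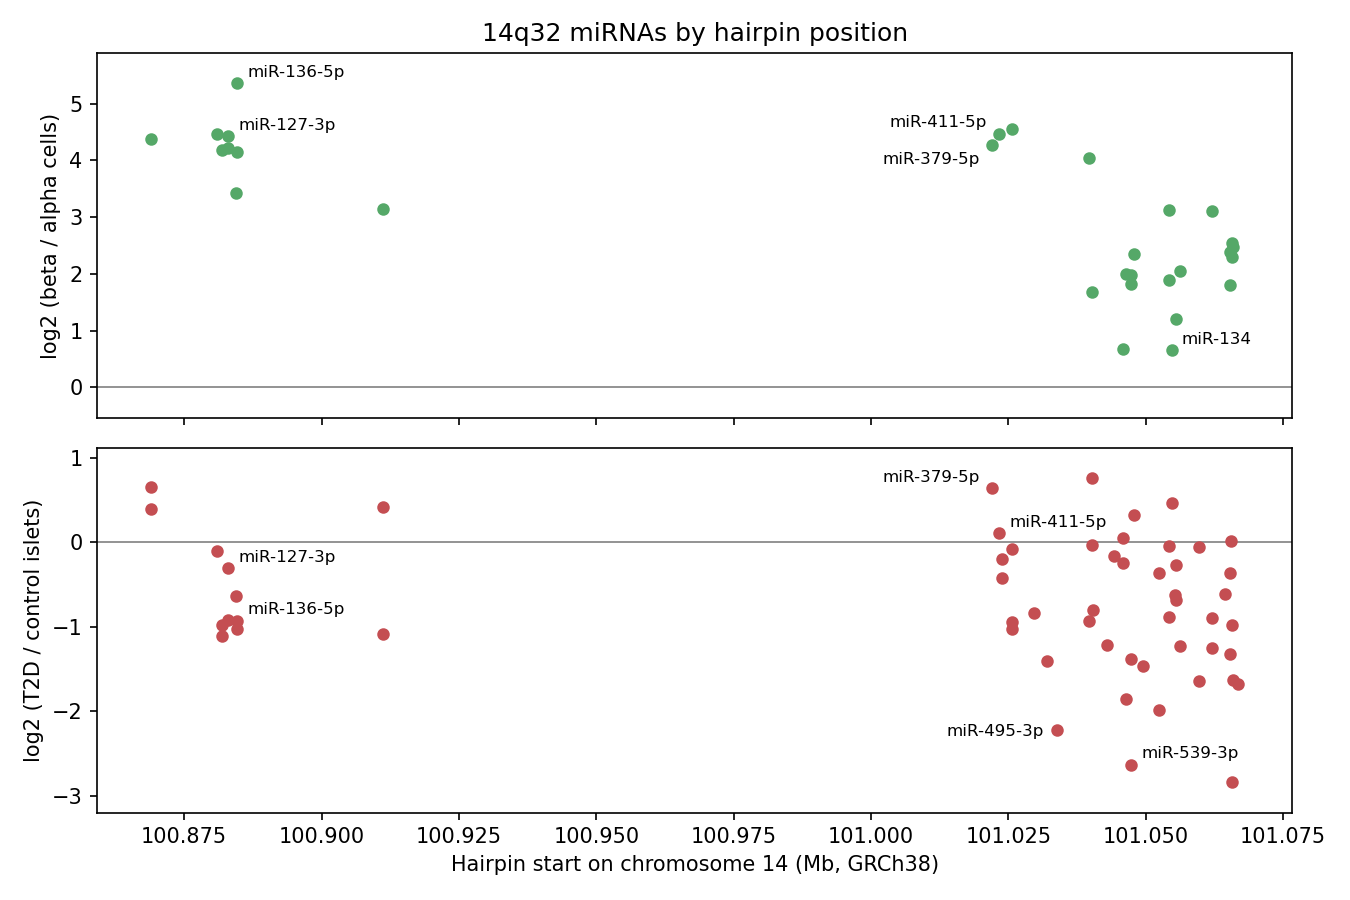
14q32 miRNAs over the minimum level or tested, by the start of their hairpin on chromosome 14 (Mb, GRCh38), with the log2 ratio of beta over alpha cells above (30 miRNAs, 1 library each) and the log2 fold change of T2D over control islets beneath (56 miRNAs, 4 and 3 libraries). All points of the upper panel lie above 0, and 46 of the 56 in the lower panel lie below 0.

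The glucose series asked whether miRNA levels in whole islets follow the glucose concentration. Levels at 16.7 and at 1 mM glucose were close for most miRNAs, and 14q32 miRNAs as a group were nearly level. Of the miRNAs with a mean of at least 50 RPM, which held 99.2% of the reads, 4 were at least 2-fold higher at 16.7 mM than at 1 mM and 24 at least 2-fold lower, and the median log2 ratio of all was 0.04. The inflammation-associated miR-21 and miR-146b were moderately higher at 16.7 mM, as was miR-148a of the acinar list, and a set of miRNAs with late miRBase numbers, such as miR-3168 and miR-5698-3p, was lower.

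The highest ratio belonged to miR-1282, at 89.8 RPM at 1 mM, 94.5 RPM at 5.56 mM and 1753 RPM at 16.7 mM, which is 19.5-fold from 1 to 16.7 mM (17.9 to 21.3). miR-670-3p (3.20-fold), miR-148b-5p (2.12-fold) and miR-181c-3p (2.06-fold) were the others past 2-fold, and the next were miR-500a-3p (1.97-fold), miR-92a-1-3p (1.97-fold, and 2.02-fold summed with miR-92a-2-3p), miR-21-3p (1.86-fold), miR-1307-5p (1.83-fold), miR-505-3p (1.76-fold) and let-7f-1-3p (1.76-fold). The lowest ratio belonged to miR-365b-3p, at 330.4 RPM at 1 mM, 24 RPM at 5.56 mM and 8.86 RPM at 16.7 mM, or 37.3-fold lower at 16.7 than at 1 mM (31.0-fold at the lower bound, and a ratio of 30.8 summed with miR-365a-3p, of the same sequence). miR-3938 was 21.5-fold lower, miR-711 17.6-fold, miR-194-1-3p 15.7-fold, miR-4459-3p 10.2-fold, miR-5698-3p 7.89-fold, miR-3168 6.61-fold, miR-1247-3p 6.50-fold, miR-3613-5p 5.56-fold and miR-4634 5.40-fold. miR-3168 was the most abundant of these, at 6799, 8242 and 1029 RPM at 1, 5.56 and 16.7 mM. Chosen after its values were seen, miR-99b-5p had the highest level of the 24, at 76305, 40057 and 32929 RPM at 1, 5.56 and 16.7 mM.

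**Figure D2:**
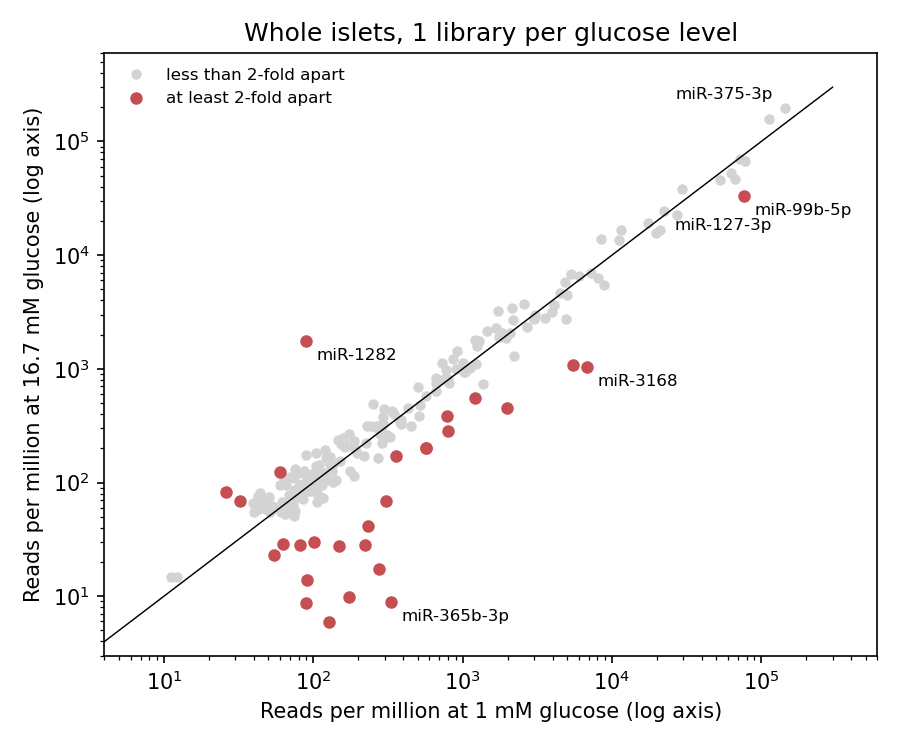
RPM of miRNAs with a mean of at least 50 RPM in whole islets after 16 hours at 1 mM glucose (horizontal, log axis) and at 16.7 mM glucose (vertical, log axis), 1 library each, with the line of equality. The 28 miRNAs at least 2-fold apart are in red, 24 of them under the line and 4 over it.

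The 5.56 mM library did not always lie between the others. It lay between them for 11 of the 24 lower miRNAs and for 4 of the 4 higher ones, and for 13 of the 24 it was at or above the 1 mM value. Between 16.7 and 5.56 mM, 1 miRNA was at least 2-fold higher (miR-1282) and 20 were lower. Between 5.56 and 1 mM, 7 were higher and 4 lower, the 4 being miR-365b-3p, miR-711, miR-4634 and miR-501-3p, a list chosen after its values were seen. miR-138-2-3p, also singled out after its values were seen, stood at 1969, 4405 and 451.4 RPM at 1, 5.56 and 16.7 mM.

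In the glucose series 22 of the 14q32 miRNAs passed the minimum. Of these, 17 were above 0 in the ratio of 16.7 over 1 mM, 0 were at least 2-fold apart, and their median log2 ratio was 0.20, at percentile 88.53 of matched random lists. miR-127-3p stood at 22206, 29285 and 24295 RPM at 1, 5.56 and 16.7 mM, miR-411-5p at 915, 1382 and 1432 RPM, miR-379-5p at 511.98, 426 and 387 RPM, miR-136-3p at 725, 1008 and 1133 RPM, and miR-432-5p at 338, 441 and 425 RPM. The locus supplied 3.14% of the reads at 1 mM (3.13% to 3.16%), 3.99% at 5.56 mM and 3.52% at 16.7 mM (3.51% to 3.53%). The medians of the other glucose contrasts were 0.05 for 16.7 over 5.56 mM (percentile 55.38) and 0.18 for 5.56 over 1 mM (percentile 96.66).

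The 5 miRNAs with the highest mean level over the 3 libraries moved by less than 2-fold from 1 to 16.7 mM, unlike miR-99b-5p. miR-375-3p stood at 144777 and 197785 RPM, miR-148a-3p at 112462 and 158062 RPM, miR-192-5p at 77605 and 66939.7 RPM, miR-27b-3p at 71582 and 69886 RPM and miR-141-3p at 63105 and 52337 RPM. The log2 ratio of miR-27b-3p, −0.03, turned to 0.06 when the most abundant miRNA was left out of the totals. miR-184-3p (664 and 754 RPM), miR-217 (109.97 and 141.5 RPM) and miR-216a-5p (295 and 273 RPM) were also close, and so was miR-132-3p (794 and 813 RPM), whose log2 ratio of 0.03 turned to −0.01 with TMM. miR-212-3p stood at 104 and 139.9 RPM.

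Of the lists, the inflammation-associated one had the highest percentile, with a median log2 ratio of 0.53 over 4 members (percentile 99.38). miR-21-5p stood at 29244 RPM at 1 mM and 38046 RPM at 16.7 mM and miR-146b-5p at 2149.5 and 3452 RPM. The acinar list had a median of 0.43 over 6 members (percentile 98.36), with miR-216b-3p apart from it at 306 and 69.1 RPM, and the miR-17-92 list a median of 0.47 over 7 (percentile 97.05). Medians of the rest were 0.32 for the islet-enriched list (percentile 80.39), 0.13 for miR-183 cluster (61.35), 0.04 for the miR-200 family (60.87), −0.05 for let-7/98 (32.82), 0.14 for miR-29 (55.13), 0.17 for miR-30 (80.54) and 0.03 for miR-132 and miR-212 (47.61). With fewer than 3 members over the minimum, the endothelial (0.40), mesenchymal (−0.13), other imprinted (−0.05), white blood cell (−0.38) and miR-34 (0.18) lists had no percentile, and the red blood cell, muscle and liver, C19MC and miR-506 lists had no member over it. Some miRNAs encoded by several genes were low in the glucose table. let-7a summed to 63.2 to 109.0 RPM, miR-7 to 95 to 123.6 RPM, miR-16 to 18.2 to 28.2 RPM and miR-103a to 3.7 to 9.1 RPM, against 42197, 74878, 4276.0 and 3997.4 RPM in the alpha cell library. Whether reads mapping to several genes were left out of that table is not given in the sources used here, so the levels of such miRNAs and the let-7/98 median are not read as levels in islets. miR-376a-1-5p (12.8 to 18.3 RPM) and miR-495-5p (8.61 to 9.59 RPM) lay below the minimum. miR-451a was listed at 0 at every glucose level.

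The comparison of T2D with control islets asked which miRNAs differ in diabetes, the 14q32 locus first. miRNAs of the 14q32 locus were lower in T2D islets as a group, with 46 of 56 tested members lower and a median 1.77-fold lower (log2 −0.82). The share of reads from the locus was 0.924% ± 0.116 (SD, n = 4) in T2D and 2.30% ± 0.522 (SD, n = 3) in control islets, and each T2D library lay below each control library. These shares were not scaled by TMM, unlike the fold changes. Dividing by the TMM factors, 0.637 for T2D library 1 and 1.745 for control library 1, would bring these 2 libraries close together. Full separation is thus shown for unscaled shares only. In contrast, all 12 tested miRNAs of the miR-30 family were higher in T2D islets, with a median log2 fold change of 1.09. No single miRNA passed the threshold over all miRNAs tested.

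After the filter 405 miRNAs were tested with limma and 257 were left out. The number with an adjusted p under 0.05 was 0, the smallest adjusted p being 0.136. At an unadjusted p under 0.05 there were 49, where 20.2 would be expected by chance, and limma-voom on estimated reads gave 0 adjusted and 84 unadjusted. Of the 49, 23 were higher and 26 lower in T2D, and 14 of the 26 but 0 of the 23 belonged to the 14q32 list. The values of the groups did not overlap for 48 miRNAs (11.9%), where chance gives 5.7%. Both chance figures are averages, and miRNAs of the same libraries need not be independent. Of the 35 splits of the 7 libraries, 5, the real one included, gave at least 49 at an unadjusted p under 0.05. Without control library 1, whose TMM factor of 1.75 stood apart from the 0.637 to 1.05 of the other libraries, 12 miRNAs passed, 7 higher and 5 lower with 4 of them in the 14q32 list, and of the 5 miRNAs with the smallest p in all libraries miR-30a-5p and miR-495-3p were among the 12, while miR-539-3p, miR-7-3-5p and miR-656-3p were not. The 49 also hung on single libraries, with 81 (42 higher, 39 lower) without control library 1, 47 (32 higher, 15 lower) without control library 2, 36 (13 higher, 23 lower) without T2D library 2 and 39 (15 higher, 24 lower) without T2D library 3. With entries of 1 mature sequence summed there were 48, with 18 higher and 30 lower. Control library 1 also differed from the other controls in its log2 levels. Its correlation (Pearson's r) was 0.863 and 0.879 with them and 0.864 to 0.937 with the T2D libraries, while control libraries 2 and 3 correlated at 0.941. It was thus closer to T2D library 1 than to either other control, which limits each donor result. The p-values measure the spread between these donors as labelled. With library totals alone in place of TMM, the median of all tested miRNAs moved from 0.10 to −0.30, and 6 were higher and 49 lower at an unadjusted p under 0.05.

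The 5 miRNAs with the smallest p, none of which passed over all miRNAs, were led by miR-539-3p. Its scaled level was 138 ± 56.3 RPM (SD, n = 4) in T2D and 813 ± 248 RPM (SD, n = 3) in control islets, a log2 fold change of −2.63 (SE 0.565, adjusted p = 0.136). miR-30a-5p stood at 5623 ± 2186 RPM in T2D and 1009 ± 205.9 RPM in control islets (log2 2.40, SE 0.524, adjusted p = 0.136). miR-495-3p stood at 138 ± 57.4 RPM against 667 ± 294 RPM (log2 −2.22, SE 0.560, adjusted p = 0.163). miR-7-3-5p stood at 380.2 ± 162 RPM against 85.92 ± 74.5 RPM (log2 2.35, SE 0.632, adjusted p = 0.163). It is 1 of 3 entries of the same mature sequence and made up 3.12% of their sum in T2D and 1.44% in control islets, and the sum had a log2 fold change of 1.21 (adjusted p = 0.467). miR-656-3p stood at 3.54 ± 1.503 RPM against 13.1 ± 3.27 RPM (log2 −1.67, SE 0.456, adjusted p = 0.163). For each of the 5 the T2D and control values did not overlap.

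**Figure D3:**
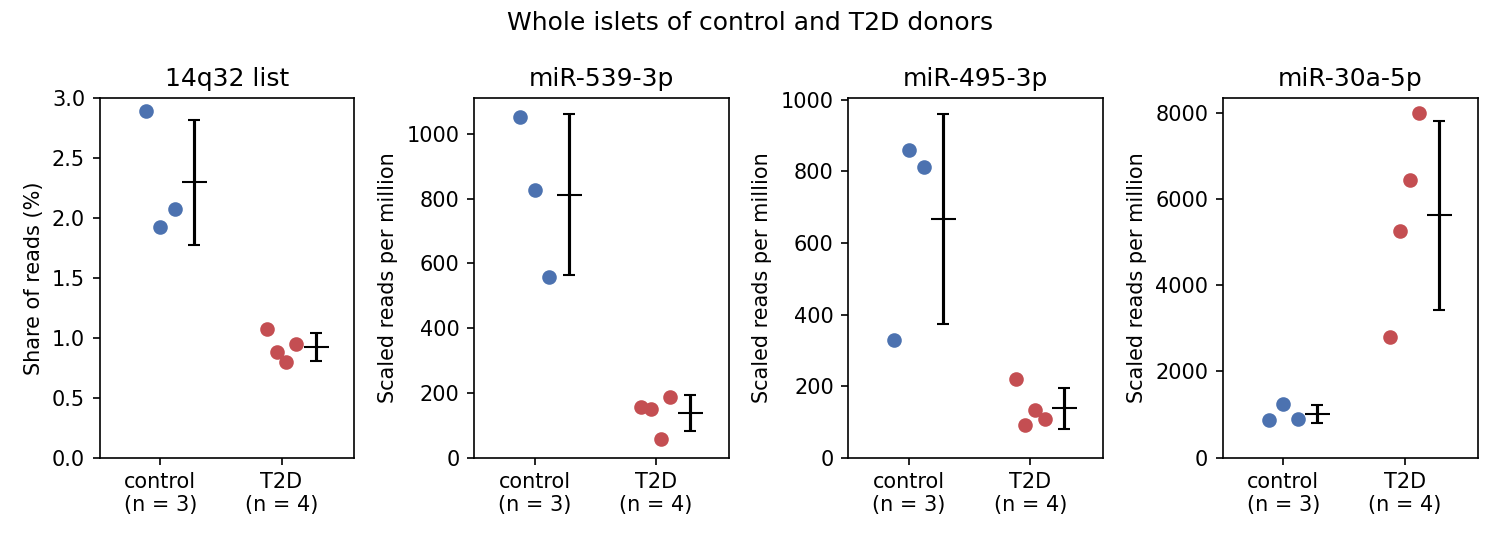
Share of reads from the 14q32 list (%) and TMM-scaled RPM of miR-539-3p, miR-495-3p and miR-30a-5p in each library of control (n = 3) and T2D (n = 4) islets, with the mean and SD as bars. The T2D shares of the locus lie between 0.798% and 1.07% and the control shares between 1.93% and 2.90%.

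As a set, the 14q32 list passed the test against all other miRNAs (camera, adjusted p = 1.8e-10 with the preset correlation of 0.01). It did not pass with a correlation estimated from these libraries (adjusted p = 0.167 with an estimated correlation). The self-contained test fry gave an adjusted p of 0.129 for one direction and 0.00578 for change in either direction. The number of members called was 0 over all miRNAs and 5 adjusted over the list alone, which is not independent evidence. The 5 were miR-539-3p, miR-495-3p, miR-656-3p, miR-369-3p (70.3 ± 43.1 RPM in T2D, 612 ± 495.3 RPM in control) and miR-487b-3p (203 ± 89.5 RPM, 695 ± 53.9 RPM), the last pair chosen after their values were seen. The most abundant members showed less. miR-432-5p stood at 2044 ± 1287 RPM in T2D and 3872 ± 2849 RPM in control islets, miR-127-3p at 1819.8 ± 135 RPM and 2743 ± 1685 RPM, miR-433-3p at 804 ± 421 RPM and 1556 ± 710 RPM and miR-485-5p at 1179 ± 958 RPM and 1631 ± 882 RPM. miR-136-5p had a log2 fold change of −0.93, miR-379-5p of 0.64, and miR-411-5p of 0.11, which turned to −0.30 with library totals alone. miR-127-3p, at −0.31, turned to 0.12 without control library 3. miR-376a-1-5p was below the filter. The exact permutation test on the unscaled shares of reads gave p = 0.0286, the smallest that 35 splits allow, and an adjusted p of 0.271 over the lists. The share from white blood cell markers moved with it, at 0.00708% ± 0.00172 in T2D and 0.0133% ± 0.00276 in control islets, each T2D library lying below each control library (log2 −0.92, exact permutation p = 0.0286, adjusted p = 0.271).

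The miR-30 family rose as a set (camera, adjusted p = 0.000371), and the call was lost with an estimated correlation (adjusted p = 0.167 with an estimated correlation) but held with fry (adjusted p = 0.0234). The family was 12 of 12 higher with TMM and 9 of 12 with library totals alone. Its share of reads was 1.33% ± 0.525 in T2D and 0.738% ± 0.492 in control islets and overlapped between the groups (exact permutation p = 0.2, adjusted p = 0.76). The number called was 0 over all miRNAs and 1 adjusted over the list alone (miR-30a-5p). miR-30d-5p stood at 3271 ± 1541 RPM in T2D and 1148 ± 788 RPM in control islets (log2 1.61), miR-30a-3p at 3172 ± 1078 RPM and 1799.9 ± 1527 RPM (log2 1.09) and miR-30e-3p at 1360.2 ± 245 RPM and 1228 ± 617 RPM (log2 0.25, and −0.17 with library totals alone).

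The acinar list, markers of the exocrine pancreas, rose with all 7 tested members higher and a median log2 fold change of 1.33 (adjusted p = 0.0055; adjusted p = 0.399 with an estimated correlation). miR-148a-3p stood at 4838 ± 3650 RPM in T2D and 1795 ± 1311 RPM in control islets, miR-217 at 2179 ± 1991 RPM and 1233 ± 934 RPM, miR-216b-5p at 944 ± 800 RPM and 339 ± 136.5 RPM and miR-216a-3p at 100.1 ± 98.8 RPM and 29.6 ± 28.1 RPM. T2D library 4 as the table numbers it held the highest level of each of these 4, and the call was lost without it (adjusted p = 0.0589) and without control library 2 (adjusted p = 0.106). The share of reads was 0.776% ± 0.71 in T2D and 0.404% ± 0.232 in control islets (exact permutation p = 0.486). The number called was 0 over all miRNAs and 1 adjusted over the list alone, miR-216a-5p, named after its values were seen.

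miR-132 and miR-212, transcribed together and induced by cAMP and neuronal activity, fell as a set, with all 4 arms lower and a median log2 fold change of −1.08 (adjusted p = 0.0157; adjusted p = 0.399 with an estimated correlation). miR-132-3p stood at 60.6 ± 43.8 RPM in T2D and 144.7 ± 87.01 RPM in control islets, miR-212-5p at 115 ± 54.2 RPM and 198.99 ± 16.9 RPM, miR-132-5p at 59.2 ± 14.1 RPM and 92.5 ± 7.93 RPM and miR-212-3p at 7.83 ± 4.49 RPM and 23.05 ± 13.6 RPM. Their share of reads was 0.0226% ± 0.0137 in T2D and 0.0553% ± 0.0161 in control islets (exact permutation p = 0.0857). The count was 0 over all miRNAs and 0 adjusted over the list alone, and the set call was lost without T2D library 1 (adjusted p = 0.0521) or control library 3 (adjusted p = 0.0602).

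The inflammation-associated list rose by a narrow margin (6 of 7 higher, median 0.68, adjusted p = 0.042; adjusted p = 0.399 with an estimated correlation). miR-21-5p stood at 9742 ± 4781 RPM in T2D and 6226 ± 5494 RPM in control islets, miR-146b-5p at 168 ± 89.5 RPM and 132.8 ± 131 RPM and miR-21-3p at 101 ± 23.2 RPM and 74.5 ± 42.8 RPM. The count was 0 over all miRNAs and 2 adjusted over the list alone, both arms of miR-187, named after their values were seen, of which miR-187-3p stood at 39.0 ± 25.4 RPM against 6.02 ± 4.55 RPM. The share of reads was 0.977% ± 0.588 in T2D and 0.681% ± 0.535 in control islets (exact permutation p = 0.543). The set call was lost without T2D library 2, 3 or 4 (adjusted p = 0.065, 0.0649 and 0.0651) and without control library 1 (adjusted p = 0.303).

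The other lists with at least 3 tested members did not pass. Their adjusted p was 0.174 for red blood cell markers (median log2 1.05), 0.219 for miR-29 (−0.43), 0.432 for white blood cell markers (−0.40), 0.432 for let-7/98 (0.37), 0.55 for muscle and liver markers (−0.11), 0.775 for other imprinted loci (0.27) and 0.903 for miR-17-92 (0.16), miR-200 (0.17), the islet-enriched list (0.03), mesenchymal markers (−0.05, the mean of 0.10 and the test pointing up) and miR-183 cluster (0.08, and a mean of 0.02, the test pointing down). miR-29 passed without control library 1 (adjusted p = 0.0387). Members adjusted over the list alone numbered 2 for the islet-enriched list, miR-7-3-5p and, named after its values were seen, miR-7-1-3p, which went opposite ways (log2 2.35 and −1.52; 1.21 for the 3 summed entries of miR-7-5p), and 0 for the 10 others. The endothelial, miR-34 and C19MC lists had fewer than 3 tested members, with mean log2 differences of the share of reads of −1.01, 0.03 and −1.38 (adjusted p = 0.814, 0.971 and 0.543, exact permutation test), and the miR-506 list had 0 entries in the donor table. The red blood cell marker miR-451a stood at 1.75 ± 1.95 RPM in T2D and 5.11 ± 3.55 RPM in control islets, below the filter.

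The most abundant miRNAs did not separate the groups. let-7a-5p stood at 237155 ± 85584 RPM in T2D and 182105 ± 96207 RPM in control islets (log2 0.52, and −0.14 with quantile normalization). let-7b-5p stood at 191293 ± 108928 RPM and 89859 ± 42309 RPM (log2 1.05), let-7f-5p at 187723 ± 66948 RPM and 154156 ± 73513 RPM (log2 0.37, and −0.05 with library totals alone and −0.15 with quantile normalization), miR-375 at 185406 ± 72506 RPM and 121035 ± 74651 RPM (log2 0.76) and miR-320a at 39557 ± 12178 RPM and 30656 ± 7536 RPM (log2 0.35, and −0.07 with library totals alone). miR-184 stood at 242 ± 85.3 RPM and 193 ± 162 RPM and miR-7-2-5p at 8140.4 ± 6345 RPM and 4394 ± 3522 RPM. The smallest adjusted p among these 7 was 0.417, for let-7b-5p.

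The deposited table also held the authors' own comparison, which marked 5 miRNAs as up and 10 as down in T2D at a false discovery rate of at most 17.4%, with 7 of the 15 in the 14q32 list. These marks rest on the same libraries, so an overlap with them is not independent evidence. Of the 15, 11 were tested here, and each of the 11 had the same direction and an unadjusted p under 0.05 but none passed over all miRNAs. The other 4, miR-23c, miR-4716-3p, miR-544a-5p and miR-589-5p, were below the filter. miR-589-5p, chosen after its values were seen, stood at 6.15 ± 1.53 RPM in T2D and 1.37 ± 0.495 RPM in control islets. The control level is near 1 read, worth 0.764 to 1.4201 RPM there before TMM scaling, so the size of this difference is not certain.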

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

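The GC, glucose position and acinar, miR-132 and inflammation split tests were written before their outcomes were seen, and the other tests of this part and of the last part were chosen after the result was seen.

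Of 93 groups of 4 T2D libraries examined with Dixon's test, 4 held a value far from the other 3, with a gap over range above the critical value, and chance alone gives about 0.05 of the groups. miR-136-5p stood at 137.9 scaled RPM in T2D library 4 and at 65.1 to 72.43 in the others. miR-7-1-5p stood at 15380 in T2D library 3 and at 3129 to 4004 in the others. miR-92a-1-5p stood at 237.2 in T2D library 1 and at 65.91 to 75.81 in the others. The share of reads from red blood cell markers was 0.001137% in T2D library 1 and 0.002681% to 0.003102% in the others.

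The lower 14q32 level in T2D islets may not come from setting miRNAs without reads to 1 read, since the 21 members with at least 100 RPM had a median of −0.925 (−1.225 to −0.361). With the trend on hairpin GC content taken away, the median went from −0.82 to −0.634 (−0.856 to −0.301, against a bound of −0.3 set beforehand). The margin was narrow. That interval is over miRNAs and not donors, and it treats arms of 1 hairpin as independent. The test thus does not decide how much of the lower level GC content accounts for. A smaller share of beta cells is not seen in the 20 other miRNAs enriched in beta cells, whose median was 0.185 (−0.008 to 0.501) and of which 6 were lower in T2D. The 20 included miR-148a-3p of the acinar list and miR-486-5p of the red blood cell list (log2 fold change 1.33 and 1.36). Such members could hide a fall of others, and the interval is over miRNAs and not donors. A smaller share of beta cells is thus not excluded. Chance cannot be excluded, since 2 of 35 splits gave a median as large (0.82 in the real split, 0.833 in the highest other). The other was the split of the 3 deepest from the 4 shallowest libraries (0.8327). The shallowest T2D library held an unscaled share of 1.073%, below the lowest control at 1.926%. That share decides nothing, since this library was still deeper than each control and its TMM factor of 0.637 would raise it. It was also the highest T2D share, with 0.798% to 0.944% in the other T2D libraries. Depth and T2D cannot be told apart.

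The 24 miRNAs lower at 16.7 than at 1 mM glucose were weighed next. Of their counting intervals 0 reached 1, which the 2-fold bound and the depth fix in advance, so counting error was not tested by this. An order graded with glucose was not seen for the set, since the 5.56 mM library lay between the others for 45.8% (25.6% to 67.2%, against a bound of 80%). This does not exclude a graded response. The interval treats miRNAs as independent, though all come from the same 3 libraries. For 16 of the 24 the 5.56 and 1 mM values lay within 2-fold, where a difference between libraries could set the order. Entries numbered 1000 or above made up 50% of the 24 and 11.2% of the other miRNAs (Fisher's exact p = 2.2e-05, across miRNAs and not across libraries), and with 3 doubled entries such as miR-4422 and miR-4422-3p, which held nearly the same values, counted once 11 of 23 and 19 of 186 (p = 3.7e-05), so part of the set could reflect a property of such entries. In the sorted cells 4 of 9 such entries and 108 of 202 others were at least 2-fold apart (Fisher's exact p = 0.74), and with 1 library per level a response to glucose could not be separated from a difference between libraries.

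The 14q32 reads in the alpha cell library might stem from beta cells in the sort, which would carry the miR-183 cluster along. Its 3 arms had alpha to beta ratios of 3.2% to 9.17% (upper bound of the highest 9.26%). For the downstream hairpins the median ratio was 23.8% (18.28% to 35.02%), so such carry-over was not their only source, while alpha cells and other cells were not separated. For the upstream hairpins it was 5.09% (4.50% to 7.70%), below the bound of the highest arm. Carry-over alone would bring each miRNA along at about 1 ratio, so the lowest arm, at 3.2%, is the tighter bound. The upstream hairpins, each a mean over its arms and the lowest of them at 3.7%, lay above that. Taken by arm, miR-136-5p stood at 17.94 RPM in alpha cells and 736 RPM in beta cells. Its alpha to beta ratio of 0.0244 lay below that of the lowest arm. Carry-over as their only source is thus left open by the highest arm. The lowest, 1 arm in 1 library per cell type, does not settle it, since means over arms and single arms are not alike. With 1 library per cell type, the spread between sorts was not measured.

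For the other donor results, chance was tested over the same 35 splits. For the miR-30 family 1 of 35 splits, the real one, was as large (1.089, highest other 1.035), which is the smallest share this design allows. That test was chosen after the result was seen and was not adjusted for the others, and with an exact permutation p of 0.2 for the share of reads chance is not taken as excluded. It was also not excluded for acinar markers (2 of 35; 1.333, highest other 1.52), for miR-132 and miR-212 (3 of 35; 1.083, highest other 1.378) or for the inflammation-associated list (12 of 35; 0.684, highest other 1.322). Nor was it for the 49 miRNAs at an unadjusted p under 0.05 (5 of 35, highest other 65.0). For the 0 at an adjusted p under 0.05 each of the 35 splits gives at least 0 (highest other 1), so the splits test nothing. The split by depth gave 62 at an unadjusted p under 0.05.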

How the results depend on the processing

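The alternatives named in the processing were set before the data were examined, except pseudocount, common floor, quantile normalization and summed entries of 1 mature sequence, which were chosen after. DESeq2, the edgeR count test and filterByExpr need counts and were not run, and no paired analysis was made. The count of 0 miRNAs at an adjusted p under 0.05 held in each setting except without control library 1, which gave 12, and ranged from 0 to 12 over the left-out libraries. The cause was not tested. In 2 settings the 0 held narrowly, with a smallest adjusted p of 0.0506 with limma-voom and 0.0555 with limma on library totals alone. The control libraries limit what low miRNAs can show, since 1 read was worth up to 1.4201 RPM there.

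RLE, library totals alone and leaving out the most abundant miRNA shift all miRNAs nearly alike (14q32 median minus that of all −0.911 to −0.925), so the set tests could hardly change under them. Quantile normalization is not such a shift (−0.845), and the 5 lists that passed kept their direction and call. With an estimated correlation the adjusted p was 0.167 for 14q32, 0.167 for miR-30, and 0.399 for acinar markers, for miR-132 and miR-212 and for inflammation. With fry it was 0.129 for 14q32, 0.241 for acinar markers (0.236 in either direction), 0.173 for miR-132 and miR-212 (0.381) and 0.213 for inflammation (0.147), and these tests ask another question. Over the left-out libraries the adjusted p ranged from 7.0e-13 to 1.1e-05 for 14q32, from 0.000431 to 0.0053 for miR-30, from 0.000431 to 0.106 for acinar markers (0.0589 without T2D library 4, 0.106 without control library 2), from 0.000993 to 0.0602 for miR-132 and miR-212 (0.0521 without T2D library 1, 0.0602 without control library 3) and from 0.0226 to 0.303 for inflammation. Inflammation was not called without T2D library 2, 3 or 4 (0.065, 0.0649, 0.0651) or control library 1 (0.303), with the stricter filter (0.0714), limma-voom (0.117) or a pseudocount of 5 (0.0626). miR-29 was called without control library 1 (0.0387; range 0.0387 to 0.695). The cause was not tested.

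Lists that did not pass turned direction in some settings. These were the islet-enriched list without T2D library 1 (adjusted p = 0.967), T2D library 3 (0.834) or control library 3 (0.695), or with entries of 1 mature sequence summed (0.618), with a range of 0.363 to 0.967, and the miR-183 cluster with no filter (0.915), the stricter filter (0.793), or without T2D library 4 (0.869) or control library 2 (0.478), with a range of 0.303 to 0.869. They were also miR-200 with no filter (0.915), limma-voom (0.535), or without T2D library 3 (0.834), T2D library 4 (0.869) or control library 1 (0.201), with a range of 0.201 to 0.869, mesenchymal markers without T2D library 4 (0.532) or control library 3 (0.695), with a range of 0.532 to 0.937, and miR-17-92 without control library 2 (0.716) or with entries summed (0.942), with a range of 0.63 to 0.948. The cause was not tested.

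Of 40 named miRNAs followed through the alternatives, 8 turned direction, none of them past the threshold; ranges are over the left-out libraries. let-7a-5p went to −0.14 with quantile normalization and −0.0626 without control library 1, with a range of −0.0626 to 0.82. let-7f-5p went to −0.0474 with library totals alone, −0.15 with quantile normalization and −0.13 without control library 1, with a range of −0.13 to 0.63. miR-127-3p went to 0.12 without control library 3, with a range of −1.02 to 0.12, and miR-320a to −0.0678 with library totals alone. That setting moved the median of all tested miRNAs from 0.10 to −0.30, so the turn of miR-320a, seen only there, is not particular to it. miR-30e-3p went to −0.17 with library totals alone and −0.0761 without control library 2, with a range of −0.0761 to 0.62, miR-146b-5p to −0.0400 without control library 1, with a range of −0.0400 to 1.48, and miR-155-5p to 0.12 without T2D library 4 and 0.52 without control library 2, with a range of −0.75 to 0.52. miR-411-5p went to −0.30 with library totals alone, −0.20 with limma-voom, and −0.001 without T2D library 3, −0.09 without T2D library 4 and −0.24 without control library 1, with a range of −0.24 to 0.34. The cause of the other turns was not tested.

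In beta over alpha cells the counts depend on the minimum mean by construction, with 112 higher at 10 RPM, and 43 higher and 23 lower at 200 RPM. The 14q32 median was 2.46 with TMM, 3.13 at 10 RPM and 2.48 at 200 RPM. For 16.7 over 1 mM glucose, 10 were higher and 84 lower at 10 RPM, and 1 and 11 at 200 RPM, and the 14q32 median was 0.29 without the most abundant miRNA, 0.11 at 10 RPM and 0.32 at 200 RPM. For 16.7 over 5.56 mM, 2 were higher with TMM and 2 without the most abundant miRNA, 55 were lower at 10 RPM and 6 at 200 RPM, and the 14q32 median was −0.0622 at 10 RPM. For 5.56 over 1 mM, 16 were higher and 33 lower at 10 RPM, and 2 and 1 at 200 RPM, and the 14q32 median was 0.11 with TMM, 0.24 without the most abundant miRNA, 0.11 at 10 RPM and 0.29 at 200 RPM.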

Other observations

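The islet miRNA miR-7 is encoded by 3 genes, and their miR-7-5p entries summed to 15020 ± 12340 scaled RPM in T2D and 7244 ± 7349 in control islets (exact permutation p = 0.257). miR-7-3-5p made up 3.12% ± 1.31 of the sum in T2D and 1.44% ± 0.649 in control islets (exact permutation p = 0.114).

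Whether 14q32 members differ by their place in the cluster was tested as a hypothesis, with 1 value per hairpin and 100000 permutations, chosen after the result was seen except for the glucose series. Between beta and alpha cells the ratio fell from the MEG3 side onward, with Spearman's rho of −0.658 over 24 hairpins (permutation p = 0.00063, adjusted p = 0.0019 over 3 tests), and medians of 4.30 in the 12 upstream and 2.07 in the 12 downstream hairpins. For T2D against control islets rho was −0.312 over 39 hairpins (permutation p = 0.053, adjusted p = 0.08), and for glucose it was −0.338 over 20 (permutation p = 0.14, adjusted p = 0.14), which did not settle the question. The permutations treat hairpins as independent, which neighbours in 1 transcript may not be, and the values for beta and alpha cells come from 1 library each.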
